A study of Rattus norvegicus with 6 samples.

How the data were processed

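Gene expression was measured in peripancreatic adipose tissue, a visceral fat depot, of 6 Wistar rats. The labels put 3 rats on standard chow (lean 14, 18 and 19) and 3 rats on a cafeteria diet for 30 days (obese 29, 32 and 42). Per the labels' protocols the tissue was frozen in liquid nitrogen, RNA was extracted with a lipid tissue kit, and biotin-labelled cRNA was made from it. Each sample was hybridised to 1 Affymetrix rat genome expression array. Each replicate number stands for a different rat, so p-values measure the spread between these rats, including whatever handling added to it.

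The deposited values are log2 expression values per probe set, made with RMA and the affy package per the submitters' processing notes. The versions, the chip definition and which arrays were normalized together are not given in the sources used here. The table held 31099 probe sets, of which 57 controls were left out of the gene tests. Of the other 31042, the platform annotation listed 1 gene symbol for 20826, several for 436 and none for 9780. Symbols were compared with the reference gene table through the gene ID, which matched 20758 probe sets, and 0 symbols needed an update. Each of 14217 genes was represented by its probe set with the highest mean over all 6 arrays. Of these genes, 9692 had 1 probe set and 4525 had more. No filter on dim probe sets was applied. The number of arrays limits the precision.

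Obese and lean arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, constant prior, two-sided, no covariate). P-values were adjusted by the Benjamini-Hochberg method over all 14217 genes, and a gene was called at an adjusted p under 0.05. Differences are obese minus lean on the log2 scale. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.

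Genes were named by a rule set before the data were examined: the 12 called genes with the largest rise and the 12 with the largest fall among those whose groups did not overlap, filled up with the smallest unadjusted p in that direction. Symbols of uncharacterised loci were passed over. Up to 4 members of each gene list, those with the smallest p, were also named. Any other gene is stated to have been chosen after its values were seen.

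In all, 37 gene lists were fixed before the data were examined, with 771 entries, of which 677 matched a gene on the array and 94 did not. Of the matches, 2 were made through a synonym or the array's own symbol. The lists were adipocyte identity, fatty acid and triglyceride synthesis, lipolysis, fatty acid oxidation, cholesterol biosynthesis, oxidative phosphorylation, citric acid cycle, thermogenic adipocyte, adipokines, insulin signalling and glucose uptake, circadian clock, antioxidant and glutathione, hypoxia and glycolysis, unfolded protein response, heat shock, immediate early, cell cycle, ribosomal protein, extracellular matrix, Wnt ligands with their receptors and antagonists, inflammatory mediators, interferon response and MHC class II presentation. The cell type lists were macrophage, T and NK cell, B cell, mast cell, neutrophil, endothelial cell, smooth muscle cell and pericyte, adipose progenitor, mesothelial cell, skeletal muscle, erythroid cell, and pancreatic acinar, duct and islet cell. Some genes stand in several lists. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 37 lists. Members of a list were also adjusted over the list alone.

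RNA quality was taken as the difference between the 3' and 5' control probe sets of Gapdh, beta-actin and hexokinase, compared by an exact two-sided permutation test.

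The alternatives set before the data were examined were median centring, quantile normalization, genes above the median of the mean level, the mean of a gene's probe sets, every probe set on its own, an intensity trend with a robust prior, array weights, each array left out in turn, other thresholds, the acinar list mean or the B, T and NK cell list mean as a covariate, camera with an estimated correlation, and fry. After seeing the data, 4 more were added: lean 14 and obese 42 both left out, the 3' minus 5' difference as a covariate, leaving out 21 genes raised in lean 14, and leaving out 113 genes of the major histocompatibility complex (MHC) region. The latter are the rat MHC (RT1) genes and the genes that lie between them in the reference gene table.

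The gene and list tests were checked on simulated data for this comparison, with 14217 genes and the genes' own residual spread. They called 84% of 2-fold changes, 99% of 4-fold changes and 9 unchanged genes. All 5 lists of 20 genes shifted by 0.4 on the log2 scale were called, and 0 of 15 unshifted lists. The gene rates depend on how many changes were simulated and how large, because the adjusted p does, so they are not the power on the real arrays. There Slc22a3 passed at 1.99-fold, but Myl4 (3.57-fold) and Grifin (3.01-fold) did not (limma adjusted p = 0.0956 for both). Few called genes therefore do not show that few genes changed 2-fold. The simulated genes varied independently of each other within a list. The list counts therefore do not show how often the test calls an unshifted list whose genes vary together.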

Results

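Visceral fat from beside the pancreas was profiled in 3 lean Wistar rats on standard chow and 3 obese rats given an energy-rich cafeteria diet for 30 days. Wistar is an outbred strain. Each array gave log2 expression values for 31099 probe sets, with medians between 5.63 and 5.68. Correlation across probe sets, which are not independent replicates, was 0.989 to 0.991 between lean arrays, 0.983 to 0.989 between obese arrays, and 0.980 to 0.989 between lean and obese arrays. The number of arrays limits the precision, and the median standard error (SE) of a gene's difference was 0.11. The labels mark every array except obese 42 as a renewed analysis of an earlier sample.

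The comparison of obese with lean rats asks which genes this fat depot expresses differently on the cafeteria diet. Slc22a3, a transporter of organic cations and monoamines, fell by 0.99 on the log2 scale (SE 0.078), from 10.13 ± 0.050 (SD, n = 3) to 9.14 ± 0.0049 (SD, n = 3), a 1.99-fold difference. Genes of the interferon response, of macrophages, of T and NK cells and of mast cells fell as groups on the obese arrays. Genes of adipocyte identity rose as a group. So did genes that carry out or restrain lipolysis, the release of fatty acids from stored fat, and some genes stand in both lists. These group calls held at a preset correlation between genes of 0.01, and were lost with an estimated one. The estimates were 0.11 for interferon response, 0.75 for macrophage, 0.39 for T and NK cell and 0.64 for mast cell genes. For adipocyte identity and lipolysis genes they were 0.30 and 0.35. The preset p-values thus treat members as more independent than these estimates do.

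Slc22a3 (adjusted p = 0.0437) was the 1 gene of 14217 that passed limma's test, and 0 genes passed upward. It is measured by 1 probe set. At an unadjusted p under 0.05 there were 1028 higher and 879 lower genes, against 711 in all by chance. The groups did not overlap for 20.4% of genes, against 10% by chance. Without any one of lean 14, lean 18, lean 19 or obese 29 the count of called genes was 0. It was 1 without obese 32, where Hpd (2.06 higher, named after its values were seen) took the place of Slc22a3 (adjusted p = 0.0624 there), and 34 without obese 42.

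Below an adjusted p of 0.10 there were 34 genes, 20 higher and 14 lower, all without overlap between the groups. That count was 0 without lean 14, lean 18, lean 19 or obese 29, 6 without obese 32 and 104 without obese 42. Of the 34, RT1-A and Psmb8 lie in the MHC region. With that region's genes left out, an alternative chosen after seeing the data, the differences of the others were unchanged, but the adjusted p of the named ones except Slc22a3 moved to 0.1001 and the count was 1. None of the genes named in the next 2 paragraphs passed at 0.05, and their adjusted p was 0.0956 except where given.

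On the obese arrays Inhbb, which encodes the activin B subunit, was higher by 1.10 (SE 0.12), a 2.14-fold difference. Fabp3, a fatty acid binding protein of heart and muscle, was higher by 1.49 (SE 0.18). St3gal5, which makes the ganglioside GM3, was higher by 0.89, and Ak3, a mitochondrial adenylate kinase, by 0.74. Fgf18, a fibroblast growth factor, was higher by 0.96, Adamts5, a matrix protease, by 0.90, and Pmepa1, a membrane protein that restrains TGF-beta signalling, by 0.90. Myl4, a myosin light chain, was higher by 1.84 (SE 0.25) and Grifin, a galectin-related protein, by 1.59 (SE 0.18). Trim16, Stom and C10h17orf58 were higher by 0.96, 0.75 and 0.998. The dimmer probe set of Trim16 was higher by 0.56, that of C10h17orf58 by 0.74, that of Adamts5 by 0.78 and that of Ak3 by 0.69.

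RT1-A, an MHC class I gene, was lower on the obese arrays at -1.77 (SE 0.17, adjusted p = 0.0770). It is measured by 1 probe set, and values of RT1 genes are uncertain for reasons given with the MHC class II list. Psmb8, a subunit of the immunoproteasome, lay at -1.12 (SE 0.16), Ifgga2l1, an interferon-inducible GTPase, at -0.99, and Gbp4, a guanylate-binding protein, at -0.57. Ccl19, a chemokine that attracts lymphocytes, lay at -0.57, Ch25h, the cholesterol 25-hydroxylase, at -1.10 and Arhgap25 at -0.66. Avpr1a, a vasopressin receptor, lay at -1.23, Enpep, the aminopeptidase that cleaves angiotensin II, at -0.86 and Kcnj8, a potassium channel of pericytes, at -0.95. Maob, a monoamine oxidase, lay at -0.998. A second, dimmer probe set of Enpep lay at -0.19.

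**Figure D1:**
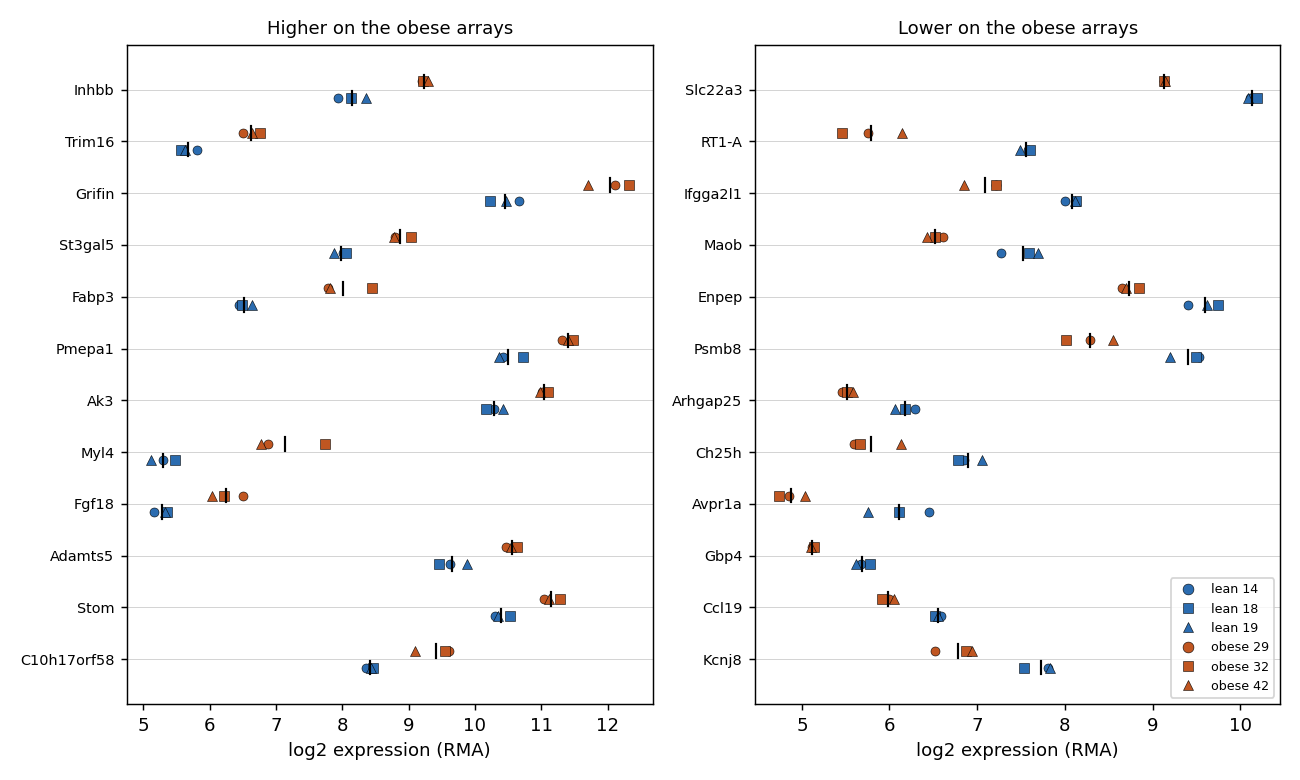
Log2 expression (x axis) of the 12 higher and 12 lower named genes on each array, blue for lean and orange for obese, with a bar at each group's mean. The groups do not overlap for any of these genes, and Slc22a3 alone passed the test.

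Interferon response genes fell as a group: all 22 measured members were lower on the obese arrays, with a median of -0.50, a 1.41-fold difference (camera adjusted p = 4.63e-10; adjusted p = 0.297 with an estimated correlation). Psmb8, Gbp2 (-0.42, SE 0.11), Mx1, an antiviral GTPase (-1.01, SE 0.27), and Bst2, an antiviral membrane protein (-0.60, SE 0.16), had the smallest p. When adjusted over the list alone, 8 members fell. Over all genes tested 0 members of this or any other list passed limma's test, and 11 interferon members had an unadjusted p under 0.05. The list mean on each obese array lay below that on each lean array.

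Macrophage genes fell as a group, with 23 of 24 members lower and a median of -0.60 (adjusted p = 1.06e-07; adjusted p = 0.592 with an estimated correlation). Lysozyme (Lyz2) lay at -0.63, the cysteine protease Ctss at -0.77, Mpeg1, a pore-forming protein, at -0.91 and Lgals3, a galectin, at -0.42. Of the macrophage genes 0 passed limma's test adjusted over the list alone, and 9 had an unadjusted p under 0.05. The lowest macrophage level was on obese 42, which also had the highest 3' minus 5' difference of the RNA control probe sets (1.28), and obese 29 lay above lean 19. The macrophage median was -0.33 (adjusted p = 0.000342) without obese 42, and -0.22 (adjusted p = 0.0212) with lean 14 and obese 42 both left out. T and NK cell genes also fell as a group, with 18 of 19 members lower and a median of -0.55 (adjusted p = 2.18e-07; adjusted p = 0.465 with an estimated correlation). Cd5 lay at -0.65, the killer cell genes Nkg7 and Klrd1 at -0.66 and -0.77, and perforin (Prf1) at -0.56. Of these genes 0 passed limma's test adjusted over the list alone, and 12 had an unadjusted p under 0.05.

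All 10 mast cell genes were lower, with a median of -0.70 (adjusted p = 1.17e-05; adjusted p = 0.481 with an estimated correlation). Of them 3 fell when adjusted over the list alone: the growth factor receptor Kit (-0.66, SE 0.16), the IgE receptor subunit Ms4a2 (-0.84, SE 0.21) and chymase (Cma1, -0.73, SE 0.20). B cell genes had 9 of 11 members lower and a median of -0.40 (adjusted p = 0.0247; adjusted p = 0.645 with an estimated correlation), with Fcmr at -0.80 and Cd37 at -0.65. No B cell gene passed limma's test adjusted over the list alone, and 2 had an unadjusted p under 0.05. The B cell call was lost without lean 18 (-0.27, adjusted p = 0.126), without obese 32 (-0.17, adjusted p = 0.261) and with lean 14 and obese 42 both left out (-0.34, adjusted p = 0.0576). With the B, T and NK cell level as a covariate the mast cell call was lost (-0.20, adjusted p = 0.246). That covariate is the mean of the B, T and NK cell genes themselves, so the loss of their own calls under it (T and NK cell -0.073, B cell 0.18) follows from its construction.

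Of 8 MHC class II presentation genes, 7 were lower, with a median of -0.66 (adjusted p = 1.17e-05; adjusted p = 0.465 with an estimated correlation). A fall adjusted over the list alone was called for 6, among them RT1-Db1 (-0.71, SE 0.12), RT1-Da (-0.74, SE 0.18), RT1-Ba (-1.32, SE 0.29) and the invariant chain Cd74 (-0.50, SE 0.10). RT1 genes belong to a family of similar and highly variable genes, and probe sets of 2 of the 6 RT1 genes with several lay over 1 log2 unit apart. The other probe sets of RT1-Ba lay at -0.55, 0.037 and 0.23. RT1-Bb, named after its values were seen, lay at 0.15 on its brighter probe set. On the dimmer one it lay at 8.52 to 8.83 on the lean and 3.92 to 4.12 on the obese arrays, the latter below each array's lower quartile (4.41 to 4.49), and no size is given for that difference. Other RT1 genes, named after their values were seen, went both ways, with RT1-CE10 at 1.21 (SE 0.68) and RT1-T24-4 at -1.95 (SE 0.53). RT1-CE10 lay at 7.62 on lean 18, against 10.30 on lean 14 and 10.36 on lean 19. RT1 values, that of RT1-A included, and this list are therefore uncertain. Cd74 is not an RT1 gene, and the interferon response call was kept without the MHC region genes (-0.50, adjusted p = 2.91e-08).

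Inflammatory mediators, which are cytokines, chemokines and their regulators, fell as a group, with 25 of 31 members lower and a median of -0.17 (adjusted p = 0.00182; adjusted p = 0.297 with an estimated correlation). The chemokine Ccl5 lay at -1.15, the NF-kappaB inhibitor Nfkbia at -0.55 and the anti-inflammatory cytokine Il10 at -0.45, while tumour necrosis factor (Tnf) was higher by 0.28. Of the mediators 0 passed limma's test adjusted over the list alone, and 1 higher and 6 lower members had an unadjusted p under 0.05.

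Adipocyte identity genes rose as a group on the obese arrays, with 20 of 23 higher and a median of 0.24 (adjusted p = 3.50e-06; adjusted p = 0.465 with an estimated correlation). Of these 9 rose when adjusted over the list alone, among them the lipid droplet proteins Plin4 (0.86, SE 0.13) and Cidec (0.44, SE 0.094), the glucose transporter regulator Trarg1 (0.40, SE 0.10) and Pck1 (0.42, SE 0.12), which serves glycerol formation in fat. All 13 lipolysis genes were higher, with a median of 0.43 (camera adjusted p = 4.63e-06, and 0.465 with an estimated correlation). The list holds inhibitors of lipolysis, such as G0s2 and Pde3b, as well as lipases, so the rise gives no direction for lipolysis itself. Pnpla2, Lipe, Plin1, Adrb3, Aqp7 and Fabp4 stand in both lists, so the calls of adipocyte identity and lipolysis are not independent. Of the lipolysis genes 7 rose when adjusted over the list alone, among them monoglyceride lipase (Mgll, 0.75, SE 0.15), the protein kinase A subunit Prkar2b (0.51, SE 0.10), perilipin 1 (Plin1, 0.46, SE 0.13) and the lipase cofactor Abhd5 (0.58, SE 0.17). Adipocyte identity and lipolysis levels were both lowest on lean 14 (-0.26 and -0.36 from the mean of the 6 arrays), the array that carried pancreatic acinar transcripts, and macrophage, T and NK cell and mast cell levels were highest there. Without lean 14 the medians were 0.23 and 0.31, and both lists stayed called (adjusted p = 5.04e-05 for each). Leptin (Lep), named after its values were seen, was higher by 0.98 (SE 0.47, adjusted p = 0.414), at 10.42 on obese 29, 10.75 on obese 32 and 8.80 on obese 42 against 8.72 to 9.23 on the lean arrays.

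Fatty acid oxidation genes had 20 of 23 members higher and a median of 0.20 (adjusted p = 0.00251; adjusted p = 0.679 with an estimated correlation). A rise adjusted over the list alone was called for 2, Acsl1 (0.47, SE 0.084), which activates fatty acids, and Cpt1b (0.55, SE 0.12), which carries them into mitochondria. Without lean 14 the median was 0.11 (adjusted p = 0.0216), and the call was lost without obese 32 (0.094, adjusted p = 0.256); with the B, T and NK cell level as a covariate the median lay at -0.060 (adjusted p = 0.672). Thermogenic adipocyte genes, of which 10 of 15 were higher, passed narrowly with a median of 0.14 (adjusted p = 0.0483; adjusted p = 0.465 with an estimated correlation), and adjusted over the list alone Fabp3 and Cpt1b rose. Cpt1b stands in both lists. The mean level of the thermogenic genes was 5.03 to 5.36 across arrays, below the array medians of 5.63 to 5.68. Cholesterol biosynthesis genes, of which 17 of 19 were higher, also passed narrowly with a median of 0.13 (adjusted p = 0.04999; adjusted p = 0.772 with an estimated correlation). Insig1 (0.84, SE 0.18), a sterol-regulated restraint on the pathway, was the 1 gene that rose when adjusted over the list alone. These calls were lost in 13 of 17 and 12 of 18 settings with the preset correlation. Without lean 14 the medians were 0.073 (adjusted p = 0.139) and 0.040 (adjusted p = 0.230). The thermogenic call was also lost without obese 29 (0.086, adjusted p = 0.0512) or obese 42 (0.098, adjusted p = 0.105), and the cholesterol call without lean 19 (0.11, adjusted p = 0.180), obese 29 (0.15, adjusted p = 0.0599) or obese 32 (0.010, adjusted p = 0.673). The cholesterol median was 0.24 without lean 18 and 0.28 without obese 42.

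Extracellular matrix genes rose as a group, with 28 of 34 higher and a median of 0.18 (adjusted p = 0.00247; adjusted p = 0.465 with an estimated correlation). Collagens Col5a3 and Col18a1 were higher by 0.91 (SE 0.21) and 0.35 (SE 0.11), periostin (Postn) was higher by 0.92 (SE 0.26), and tenascin C (Tnc) lay at -1.30 (SE 0.46). Of the matrix genes 0 passed limma's test adjusted over the list alone, and 6 higher and 1 lower members had an unadjusted p under 0.05. All 16 ribosomal protein genes were lower, with a median of -0.14 (adjusted p = 8.43e-05; adjusted p = 0.592 with an estimated correlation). Rpl6 lay at -0.23 and Rps3 at -0.22, 0 members passed limma's test adjusted over the list alone, and 2 had an unadjusted p under 0.05. With the B, T and NK cell level as a covariate the ribosomal median was -0.055 (adjusted p = 0.127).

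Smooth muscle cell and pericyte genes had 13 of 15 members lower and a median of -0.78 (adjusted p = 0.00249; adjusted p = 0.617 with an estimated correlation). When adjusted over the list alone 2 fell, Kcnj8 (-0.95, SE 0.14) and Rgs5 (-0.78, SE 0.18), a regulator of G protein signalling in pericytes. The list's level was highest on lean 19, and without that array the median was -0.17 (adjusted p = 0.211). Pancreatic acinar cell genes, which encode digestive enzymes, had 22 of 26 members lower and a median of -0.99 (adjusted p = 0.0128; adjusted p = 0.772 with an estimated correlation). Their level was high on lean 14 alone, where trypsinogen (Prss1) reached 10.62 against 4.30 to 5.07 elsewhere and amylase (Amy2a3) 10.17 against 3.22 to 3.89, both named after their values were seen. Without lean 14 the acinar median was 0.11 and the test called a rise (adjusted p = 0.000620); without obese 32 the call was lost (-0.95, adjusted p = 0.0672), and without lean 19 the median was -1.54. Adjusted over the list alone 0 acinar genes passed limma's test, and 0 had an unadjusted p under 0.05.

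**Figure D2:**
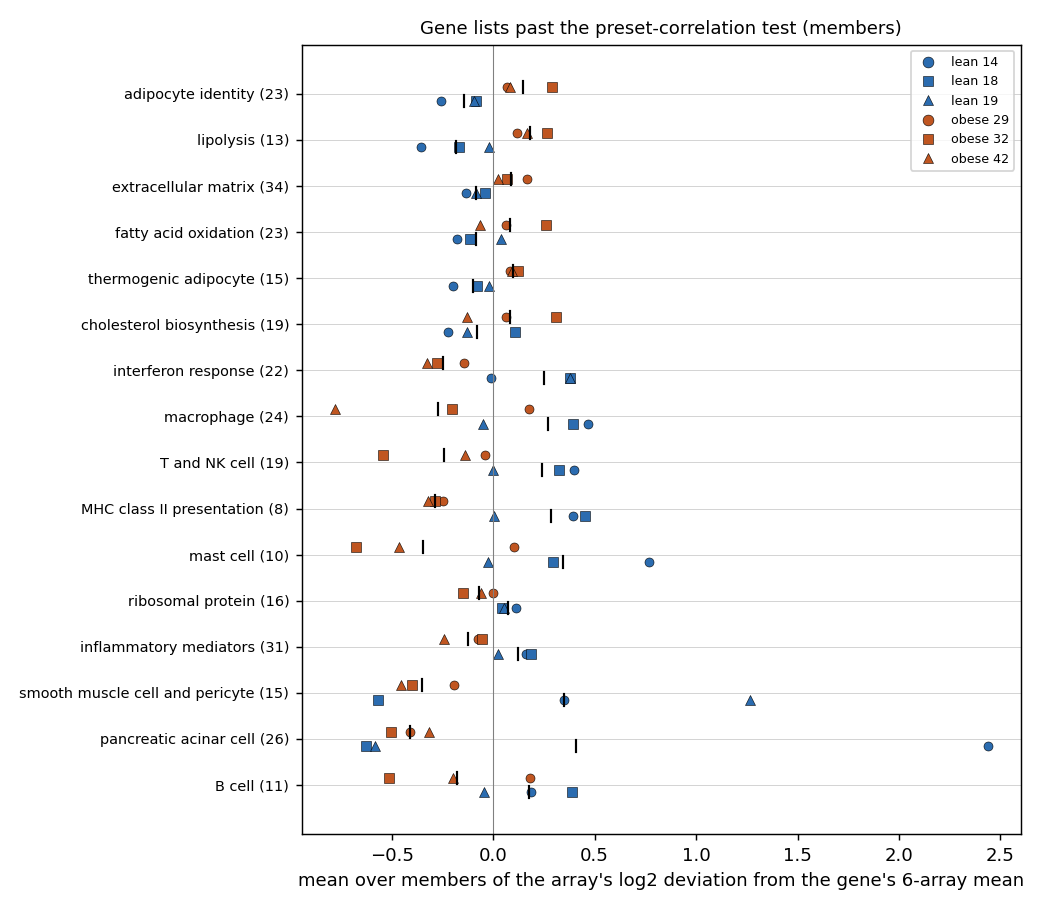
Mean over each list's members of an array's log2 deviation from the gene's mean over the 6 arrays (x axis), for the 16 lists past the test at a preset correlation, blue for lean and orange for obese, with a bar at each group's mean. Arrays of the groups overlap for fatty acid oxidation, cholesterol biosynthesis, macrophage, mast cell, B cell, smooth muscle and acinar genes, with the acinar level high on lean 14 alone, and do not overlap for the other lists.

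In all, 16 of 37 lists were called, 6 higher and 10 lower. With camera's estimated correlation 0 were called, with 2 at an unadjusted p under 0.05, and limma's fry, which asks whether members move one way on balance, called 0, with 10 under 0.05. The other 21 lists did not pass. Circadian clock genes had a median of 0.11 (adjusted p = 0.231), and adjusted over the list alone the clock repressors Per2 (0.96, SE 0.17) and Cry1 (0.50, SE 0.12) rose and Nr1d2 (-0.38, SE 0.093) fell. Insulin signalling and glucose uptake genes had a median of -0.063 (adjusted p = 0.585), and adjusted over the list alone Grb14, an inhibitor of the insulin receptor, rose by 1.06 (SE 0.15). In the other 19 lists 0 members passed limma's test adjusted over the list alone, and 22 higher and 12 lower members had an unadjusted p under 0.05.

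Fatty acid and triglyceride synthesis genes had a median of -0.093 (adjusted p = 0.318), with the elongase Elovl6 at -1.40 (SE 0.45), the desaturase Fads2 at -0.40 and the triglyceride enzymes Lpin1 and Dgat2 higher by 0.40 and 0.36. This list was called lower without lean 14 (-0.27, adjusted p = 0.00206) and without obese 32 (-0.22, adjusted p = 0.0231). Medians of the other metabolic lists were 0.043 for oxidative phosphorylation (adjusted p = 0.231), 0.034 for the citric acid cycle (adjusted p = 0.820), 0.044 for hypoxia and glycolysis (adjusted p = 0.901), 0.068 for antioxidant and glutathione genes (adjusted p = 0.378) and 0.057 for adipokines (adjusted p = 0.378). The antioxidant enzyme Gpx3 was higher by 0.58 and the hypoxia gene Bnip3 by 0.47. Among stress and growth lists, the medians were -0.058 for the unfolded protein response (adjusted p = 0.526), 0.11 for heat shock (adjusted p = 0.216), 0.099 for immediate early genes (adjusted p = 0.285), 0.015 for cell cycle genes (adjusted p = 0.378) and -0.045 for Wnt ligands, receptors and antagonists (adjusted p = 0.445). Without obese 42, oxidative phosphorylation (0.14, adjusted p = 9.00e-05) and cell cycle genes (0.27, adjusted p = 0.0495) were called higher. Without obese 29, cell cycle genes were called lower (-0.35, adjusted p = 7.37e-07) and immediate early genes higher (0.32, adjusted p = 0.00796).

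Among cell type lists that did not pass, the medians were -0.17 for endothelial cells (adjusted p = 0.104), 0.013 for adipose progenitors (adjusted p = 0.855), 0.12 for mesothelial cells (adjusted p = 0.427), 0.13 for neutrophils (adjusted p = 0.849), 0.099 for skeletal muscle (adjusted p = 0.526) and 0.17 for erythroid cells (adjusted p = 0.152). Pancreatic islet and duct genes had medians of 0.092 (adjusted p = 0.113) and 0.14 (adjusted p = 0.149), and the islet level was not raised on lean 14. Endothelial genes were called lower without obese 42 (-0.37, adjusted p = 3.94e-06) and with array weights (-0.29, adjusted p = 0.00341). Mesothelial (0.25, adjusted p = 0.000731) and duct genes (0.16, adjusted p = 0.0300) were called higher without obese 32. Signs differed within some lists. Cell cycle genes had a positive median, a mean of -0.034 and a test pointing down. Skeletal muscle, neutrophil, hypoxia and citric acid cycle genes had a positive median, a negative mean (-0.033, -0.013, -0.035 and -0.00029) and a test pointing up.

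RNA quality differed between arrays more than between diets. The 3' minus 5' difference of the control probe sets was 0.94 ± 0.15 (SD, n = 3) on lean and 1.06 ± 0.19 (SD, n = 3) on obese arrays, by the mean of 3 genes (exact two-sided permutation p = 0.4, where 3 against 3 arrays cannot give less than 0.1). Obese 42 had the highest value for Gapdh (0.82 against 0.26 to 0.47) and for beta-actin (1.98 against 1.06 to 1.498), and not for hexokinase (1.04 against 1.05 to 1.33). In limma's array weights obese 42 had the lowest, 0.478. Spike-in control transcripts averaged 8.86 on lean 14 and 9.80 to 9.95 on the other arrays.

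**Figure D3:**
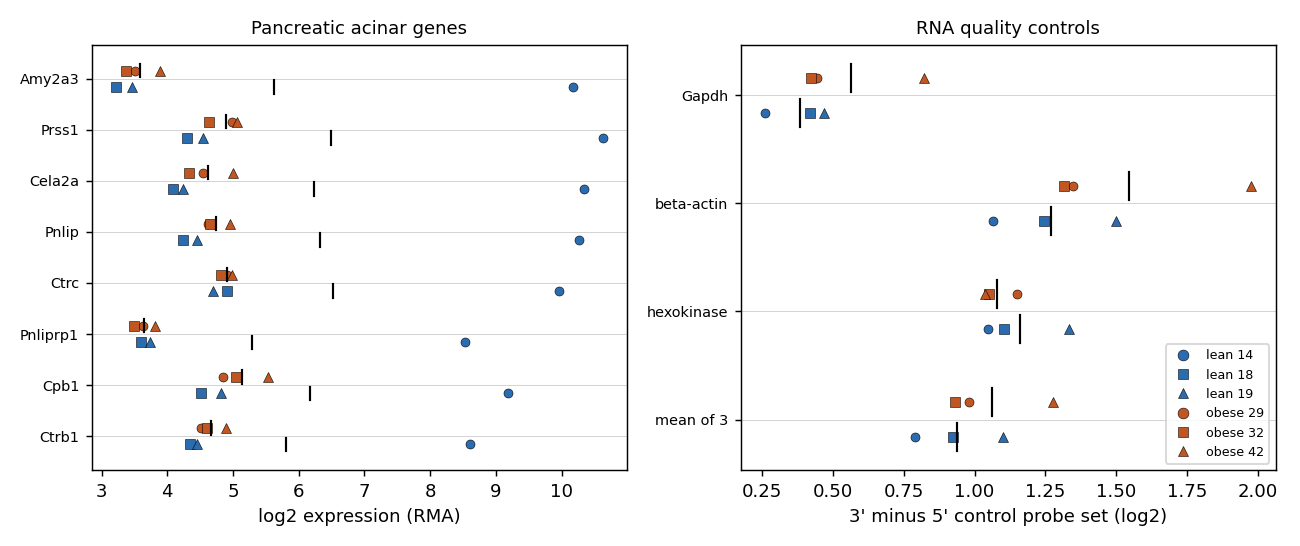
Left, log2 expression of the 8 acinar list genes most raised on lean 14; right, the 3' minus 5' control difference in log2 units per gene and as the mean of 3 genes, each per array, blue for lean and orange for obese, with a bar at each group's mean. Lean 14 alone carries high acinar transcripts, and obese 42 stands apart for Gapdh and beta-actin.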

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

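All tests of an explanation in this part were chosen after the result was seen. Outside the gene comparison, 1 probe set for which the annotation lists no single gene was higher on the obese arrays by 0.90. It lay at 7.29 ± 0.026 (SD, n = 3) against 6.39 ± 0.12 (SD, n = 3), with a limma adjusted p of 0.0983 over all probe sets, controls included. The control probe set AFFX_rat_5S_rRNA_at was higher by 0.35, at 6.25 ± 0.19 (SD, n = 3) against 5.90 ± 0.026 (SD, n = 3). It was 1 of 12 rat control probe sets in having every obese array above every lean array, an order that chance gives 5% of the time for each.

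Macrophage, T and NK cell, mast cell and MHC class II genes were lower on the obese arrays, at -0.55 over their 61 members (SE 0.22, exact permutation p = 0.2). The MHC class II members include RT1 genes, whose values are uncertain. Macrophage and mast cell members alone lay at -0.58 (SE 0.30, exact permutation p = 0.2). Whether degraded RNA on obese 42 adds to the immune difference stays open. Without that array the difference was -0.45 (SE 0.26). It was also -0.44 (SE 0.25) without lean 14 and -0.49 (SE 0.27) without obese 32, so the move is not particular to obese 42. Obese 42 is also the array not labelled a renewed analysis, so leaving it out cannot separate RNA quality from that. A larger adipocyte share of the RNA, which would dilute every other cell type alike, might give part of the immune difference. The immune difference minus that of 43 mesothelial, endothelial and progenitor genes was -0.54 (SE 0.25), and -0.36 (SE 0.21) without obese 42. The bound for this test was tightened to cover each array left out after the first value had been seen. The second value does not meet it, and neither do those without lean 14 (-0.45, SE 0.30) or without obese 32 (-0.54, SE 0.32). The 43 genes themselves lay at -0.0070 (SE 0.096) over all arrays and at -0.096 (SE 0.046) without obese 42. Smooth muscle cell and pericyte genes were not among the 43, and their median was -0.78, or -0.17 without lean 19. Non-immune cell types were thus not all flat, and the comparison does not settle dilution. Lymph node tissue in the lean samples also stays open with B cell genes at -0.35 (SE 0.24), as does a lower number or activity of immune cells on the cafeteria diet, which was not tested.

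Digestive enzyme transcripts were high on lean 14 alone. Exocrine pancreas in that sample is a candidate explanation: 17 of 26 acinar genes lay over 1 log2 unit above every other array. Outside the list 4 of 14191 genes did so, Prss3b, Rnase1l2, RT1-N2 and Nom1. The cause of the lower spike-in level on lean 14 was not tested. No biological explanation was tested, because the design gives none for a single rat.

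RT1-Bb lay at 8.52 to 8.83 on the lean arrays and 3.92 to 4.12 on the obese arrays for its dimmer probe set, the latter below each array's lower quartile (4.41 to 4.49), and at 9.64 to 10.13 on all arrays for its brighter probe set. A lower level of the whole transcript is argued against by that brighter probe set, at 0.15 (SE 0.12). Different RT1 alleles in the lean and obese rats that bind some probes differently could produce such a pattern. Among the other 5 RT1 genes with several probe sets, 20% (1, RT1-Ba) had probe sets over 1 log2 unit apart, against 0.288% of 4519 other genes (Fisher's exact p = 0.0154), but the bound of at least 2 such genes, set after the values were seen, was not met. A different transcript end or isoform on the diet also stays open and was not tested.

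The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The diet split called 1 gene, and the highest of the other splits called 0; 1 split of the 10 gave as many, the diet split itself. At an unadjusted p under 0.05 it gave 1907 genes, and the highest other 1067. It called 16 gene lists and the other splits called 6 to 18, with 3 splits, the diet split included, giving at least 16. The highest set lean 14, lean 18 and obese 29 against the rest. The number of called lists therefore does not set the diet split apart from other groupings of these arrays.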

How the results depend on the processing

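The tests that left out lean 14 and obese 42 together, used the 3' minus 5' difference as a covariate, or left out the genes raised in lean 14 or the MHC region genes were chosen after the data were seen. The number of called genes, 1, was 0 after median centring, with the acinar or the B, T and NK cell level or the 3' minus 5' difference as a covariate, with lean 14 and obese 42 both left out, and at an adjusted p under 0.01. It was 2 with the mean of a gene's probe sets, 3 with every probe set tested, 9 with array weights (6 higher, 3 lower, all 9 among the 34 below 0.10) and 34 at an adjusted p under 0.10. The gene added with the mean of probe sets was RT1-Bb (limma adjusted p = 0.000728). Its dimmer probe set also passed when every probe set was tested (limma adjusted p = 2.02e-05). Both values lie below that of Slc22a3, so its place as the only called gene depends on the choice of the brightest probe set. With single arrays left out the number of called genes ran from 0 to 34. Without obese 42, 11 of the 34 were among the first 34. The Slc22a3 difference stayed between -1.01 and -0.97 in every setting, with adjusted p from 0.0161 to 0.723. The number of called lists, 16, was 0 with an estimated correlation and 0 with fry, 14 to 18 with single arrays left out, and 12 to 19 in the other settings. Signal over background was not used here, so the limit it sets on dim genes is unknown.

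Interferon response, macrophage, MHC class II, inflammatory mediator, adipocyte identity, lipolysis and extracellular matrix lists kept their direction and their call in every setting that could be run with the preset correlation; with MHC region genes left out the MHC class II list was too short to test. Sizes moved by over 1.5 times for some of them. The macrophage median, -0.60, was -0.33 without obese 42 and with the 3' minus 5' difference as a covariate, -0.25 with the B, T and NK cell level as a covariate and -0.22 with lean 14 and obese 42 both left out. With the B, T and NK cell level as a covariate lipolysis went from 0.43 to 0.25 and MHC class II from -0.66 to -0.42, and with the genes above the median level inflammatory mediators went from -0.17 to -0.31. Among the other called lists, the thermogenic call was lost in 13 of 17 such settings, cholesterol in 12 of 18, and acinar in 6 of 17 with 2 more that turned. The acinar losses with the acinar level as a covariate (-0.016) and with the genes raised in lean 14 left out (-0.00067) follow from construction. That covariate is the mean of the acinar genes, and most of the genes left out are acinar genes. Lists not called gained a call in some settings beyond single arrays left out. With lean 14 and obese 42 both left out these were fatty acid synthesis (-0.23) and endothelial (-0.36) downward, and oxidative phosphorylation (0.11), cell cycle and erythroid (0.29) upward. With the 3' minus 5' difference they were endothelial (-0.33), oxidative phosphorylation (0.10) and erythroid (0.25), with array weights endothelial (-0.29) and oxidative phosphorylation (0.064), and with the acinar level fatty acid synthesis (-0.24). With the B, T and NK cell level they were fatty acid synthesis (-0.28), endothelial (-0.41), mesothelial (0.52) and duct (0.19). The hexokinase control alone gave -0.084 for RNA quality against 0.12 for the mean of 3 genes. In the following the direction of the list test turned, and list medians are given; the cause was not tested, except that the B cell genes are part of the B, T and NK cell covariate. With the B, T and NK cell level as a covariate: fatty acid oxidation -0.060, oxidative phosphorylation -0.072, citric acid cycle -0.11, adipokines 0.041, Wnt genes 0.095, B cell 0.18, neutrophil -0.14, skeletal muscle 0.0053, erythroid -0.027, cell cycle 0.28, unfolded protein response 0.021 and immediate early -0.079. With the acinar level as a covariate: citric acid cycle 0.028 and hypoxia -0.0089. With the mean of a gene's probe sets: adipose progenitor -0.0085 and hypoxia -0.022. Neutrophil genes turned under quantile normalization (0.090), insulin signalling with the genes above the median level (-0.042) and cell cycle under array weights (0.16). With lean 14 and obese 42 both left out: acinar 0.098, cell cycle 0.34 and unfolded protein response 0.024. With the 3' minus 5' difference as a covariate: cell cycle 0.23 and unfolded protein response 0.016.

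With single arrays left out, lists whose test turned at least once ranged from -1.54 to 0.11 (acinar), -0.059 to 0.14 (citric acid cycle), -0.35 to 0.27 (cell cycle), -0.0046 to 0.082 (hypoxia), -0.27 to 0.073 (fatty acid synthesis), -0.086 to 0.18 (neutrophil), 0.061 to 0.15 (skeletal muscle), -0.080 to -0.036 (insulin signalling), -0.049 to 0.10 (adipose progenitor), -0.073 to 0.25 (mesothelial), -0.37 to 0.097 (endothelial), -0.038 to 0.14 (oxidative phosphorylation) and -0.064 to 0.32 (immediate early).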

Other observations

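The genes in this part were chosen after their values were seen, and it reports no test of an explanation. Among the 34 genes below an adjusted p of 0.10, 10 lay outside the genes named by their p, and of these Grb14 was named from its list. Higher on the obese arrays were Dlg2, a scaffold protein of synapses (1.96, SE 0.28), the keratin Krt14 (1.49, SE 0.22), Grb14 (1.06, SE 0.15), the matrix protease Mmp23 (0.88), Cdr2 (0.86), the ceramidase Asah2 (0.85), the copper transporter Slc31a2 (0.68) and the collagen Col7a1 (0.67). Lower were the eosinophil chemokine Ccl11 (-2.19, SE 0.32) and clusterin (Clu, -0.75, SE 0.11). Limma's adjusted p was 0.0956 for 9 of them and 0.0983 for Clu.

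Ldb3, a protein of the muscle Z-disc, has 6 probe sets. A single one was higher on the obese arrays by 1.52 (SE 0.12) and passed when every probe set was tested (limma adjusted p = 0.0466). The others lay at 1.26, 1.05, 0.35, 0.12 and -0.081.

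Without obese 42, the 34 called genes included leptin (Lep, 1.58 higher, SE 0.18), the heat shock protein Cryab (1.46), the water channel Aqp1 (-0.92) and Milr1, a mast cell receptor (-2.03). Without any other single array, the count was 0 or 1.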
